A study of Mus musculus with 18 samples.

How the data were processed

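RNA of 18 livers was sequenced as stranded poly(A) libraries, per the labels' protocols. The deposited table holds whole-number scores: gene counts divided by a size factor per library and rounded by the authors, judged from the values, which lack raw library sizes. Per the submitters' processing notes, the authors used Trimmomatic 0.39, STAR 2.6.1d, Picard 2.21.7, featureCounts 1.6.5 and DESeq2 1.26.0 with mm10 (GRCm38). Whether duplicate reads were removed is not given in the sources used here. Median-ratio size factors recomputed from the table were 1.01 in every library, so the libraries were already on a common scale. Values are called scaled counts here. They are not raw counts. Reads per library could be estimated from them but were not used in a count model, and the planned fits with edgeR and DESeq2 were left out.

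Groups came from the sample titles, which give the day, the mimic and a replicate number. The analysis used all 31165 genes of the table with the coordinates the table gives. Transcript lengths and 3′ UTRs came from GENCODE M21 on the same build: 31108 gene IDs were found there, 24390 (78.4%) with identical coordinates, and 18781 with an annotated 3′ UTR. The table lists 0 mitochondrial genes and 9 genes on chromosome Y.

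Genes with a mean of 10 or more over the 18 libraries (14104, 45.3%) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups, contrasts between them and eBayes with a mean-variance trend (12 residual and 6.50 prior degrees of freedom). All 18 libraries entered, so the groups share 1 estimate of the spread. Fold changes on this scale understate changes of low genes. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The effect averaged over the 3 days and the difference of the effect between days (an F test) came from the same fit. For lists of 5 to 40 genes, 33 in all, camera was run with a preset correlation of 0.01 and with an estimated one, and fry beside it. List means per library were compared by exact permutation within a day (smallest possible p 0.1) and within all 3 days together (smallest possible p 0.00025). Seed-site genes were compared with the other genes that have an annotated 3′ UTR, and with 7-mers of the same base composition.

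The named genes follow a rule. For each mimic comparison these are the genes past the threshold whose 3 mimic values all lie on 1 side of the scrambled values, up to 10 each way, with the 5 genes of smallest p where fewer than 5 pass. For age they are the 10 largest rises and falls among genes with a mean of 100 or more. Up to 4 list members with the smallest p were eligible, and 10 targets of the microRNA family, Afp and Alb were always taken. Cyp2c50, Cyp2c37 and Ttn values outside P7 were added after their values were seen. The lists, main tests, this rule and most alternatives were fixed before the data were examined.

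Several choices came after values had been seen. Lists were picked for description partly by whether their means parted the 3 mimic from the 3 scrambled libraries. The lowering added to seed-site genes, the estimate of reads, the tests of explanations and the position of livers between P7 and P14 were all added later. The range searched for the worth of 1 read was narrowed after 2 libraries gave an ambiguous fit in a wider range. The test of a ceiling on abundant transcripts was the third tried: the first 2, on a slope and on a median ratio of variance to mean, had left the question undecided under their own bounds. The recomputation of named genes under each alternative was at first narrowed after many targets near 0 changed sign, and was then restored for every gene and list named.

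What 1 read was worth in a library was fitted from the whole numbers between 3 and 60 that are missing or doubled in the table. In 6 simulated libraries the fit missed the true value by at most 0.001. The limma script was tested on simulated data for the comparison at P14: in 14018 genes with 200 changed, it called 41.8% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 10 false calls. Each gene was drawn independently, without the trend with transcript length seen in the real libraries, so these rates may not hold for the livers. Background per kb was the sum of values over 8686 genes with a mean under 0.2 in the 16 libraries other than P7 scrambled replicates 2 and 3, divided by their summed transcript length. Alternatives were a pseudocount of 5, no filter, a mean of 50 or more, TMM scaling (own code), quantile normalization, only the libraries compared, no mean-variance trend, the replicate number as a block, covariates for Y-linked and red cell genes, and each library left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table (version 1.17.8) were used.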

Results

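Livers of newborn C57BL/6J mice were profiled by stranded mRNA sequencing after intraperitoneal injection of a synthetic mimic of the microRNA miR-497a-5p or of a scrambled mimic on postnatal days 1 and 3. Livers were taken at P5, P7 or P14. Each of the 6 groups, mimic or scrambled at each day, held 3 libraries, 18 in all, and each library is called below by its group and replicate number. The protocol names doses of 10 and 100 mg per kg, and the labels of single libraries do not repeat a dose. The table lists 31165 genes with scaled counts, and 14104 genes with a mean of 10 or more over the 18 libraries were tested. Because the labels do not say which litters the pups came from, the p-values below measure the spread between these livers.

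The scaled counts summed to between 3954400 and 4248300 per library. Missing and doubled whole numbers among the low values gave an estimate of what 1 read was worth after scaling, from 0.785 in P7 mimic replicate 3 to 1.41 in P5 scrambled replicate 2, which places the reads assigned to genes between 3006600 and 5319600. Above 0.8 reads per base of transcript lay 26 genes, 24 of them with transcripts of 500 bases or more, while Apob, with 4925 reads on average, had 0.353. Alb, the albumin gene, had an estimated 2087 reads ± 31.2 (SD, n = 18) over a transcript of 2034 bases where counting error alone gives a spread of 2.19%, or more than that SD. In all, 202 genes lay above 0.5 reads per base, these included. No pair of replicates matched within sampling noise. The squared difference over the sum of the 2 scaled counts, averaged over genes, was between 1.82 and 8.78 in the 18 pairs within groups. Counting error alone would give about the worth of 1 read, estimated above at no more than 1.41.

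**Figure D1:**
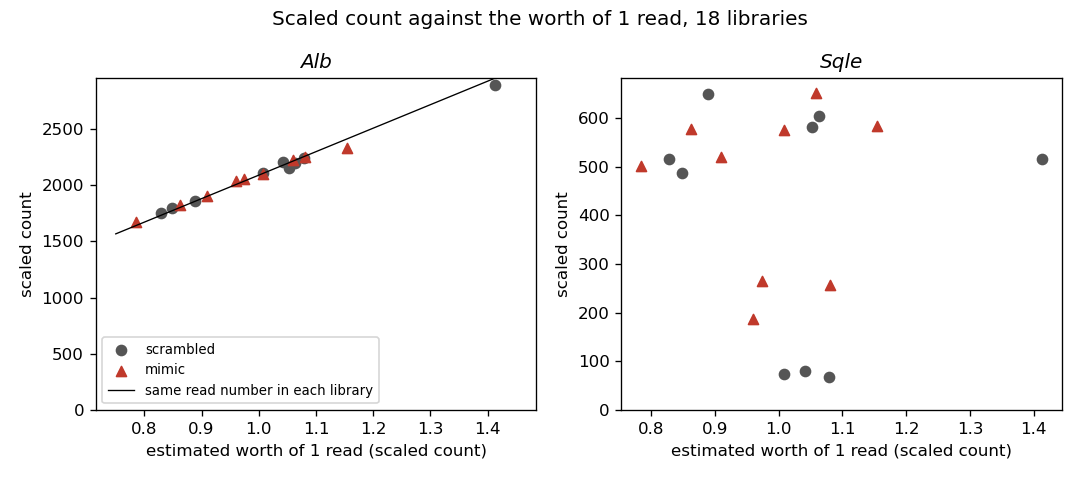
Scaled counts of Alb and Sqle (y axis, linear) against the estimated scaled count that 1 read was worth (x axis) in the 18 libraries, grey circles for scrambled and red triangles for mimic; the line marks 2087 reads in every library. Alb lies along the line, and Sqle does not.

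Age set most of the variation between livers. The first principal component of 9923 genes with a mean above 100 held 63.8% of the variance and parted the P14 livers, at scores from 34.5 to 46.2, from the earlier ones, at -29.9 to -9.29. The second held 12.6% and followed the slope of each library's values with transcript length, with Pearson's r of 0.946 between the component's score and each library's rank correlation with length. That rank correlation ran from -0.429 in P5 scrambled replicate 2 to 0.585 in P7 mimic replicate 1, and both components were computed from the same values. In P7 scrambled replicate 3, genes that were silent elsewhere carried 3.08 scaled counts per kb, against 0.168 in P7 scrambled replicate 2 and at most 0.0260 in the other 16 libraries. These genes were picked for low values in those 16 libraries, so part of the contrast is built in.

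At P14, livers given the mimic carried more transcript of the cholesterol enzyme gene Sqle and of the blood group gene Kel, and less of the cytochrome P450 gene Cyp2c54. Most other genes of cholesterol synthesis, red cell precursors and neutrophil precursors leaned higher and most matrix and contractile genes of fibroblasts leaned lower, but none of those other genes passed the threshold over all genes, and no list passed with an estimated correlation or in fry. The comparison addresses what the mimic changed 11 days after the second injection. With limma on log2(value + 1) and Benjamini-Hochberg adjustment, 3 genes passed an adjusted p of 0.05 (2 higher and 1 lower), and 763 of 14104 had an unadjusted p under 0.05. Of the 10 splits of the 6 libraries, 3 gave 3 or more genes, the real split included, so chance is not excluded for the number of calls. The count was 15 without P14 scrambled replicate 2, 16 without P14 scrambled replicate 3 and 8 without P14 mimic replicate 3, and all 3 genes were among the calls in each of those fits. With only the 6 P14 libraries in the fit, the limma adjusted p was 0.0411 for Sqle and Cyp2c54 and 0.496 for Kel, which was lost.

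Sqle (chromosome 15, 59315081 to 59331192, mm10) had scaled counts of 74.3 ± 7.02 in scrambled and 236 ± 43.0 in mimic livers at P14 (SD, n = 3 each). Its log2 difference in limma was 1.64 with SE 0.14 and an adjusted p of 4.66e-06, and it stayed past the threshold with each P14 library left out, at 1.55 to 1.80. At P7 the same gene had 535 ± 61.1 in scrambled and 577 ± 75.5 in mimic livers (SD, n = 3 each), so that the scrambled livers had dropped further by P14.

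Kel (chromosome 6, 41686330 to 41704339) had scaled counts of 3.33 ± 2.31 in scrambled and 15, 23 and 13 (SD 5.29) in mimic livers at P14 (SD, n = 3 each). The log2 difference was 2.14 (SE 0.28, limma adjusted p 0.00311), and at P7 both groups had over 400 (427 ± 94.2 and 421 ± 76.4, SD, n = 3 each). That SE pools the spread of all 6 groups, and Kel was far higher at P5 and P7. It therefore does not measure the spread at the low P14 values alone, and the call was lost with only the P14 libraries in the fit. Cyp2c54 (chromosome 19, 40037941 to 40073811) was at 161 ± 35.8 in scrambled and 34.7 ± 8.08 in mimic livers (SD, n = 3 each), a log2 difference of -2.18 (SE 0.34, limma adjusted p 0.0198). Without P14 mimic replicate 1 or 2 its limma adjusted p was 0.0956 or 0.0860. Cyp2c54 belongs to a family of near-identical neighbours among which reads can be divided. Cyp2c50 had a log2 difference of -0.56 (limma adjusted p 0.815) and Cyp2c37 one of -0.21 (limma adjusted p 0.925).

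The other genes with the smallest p at P14 were Trim10, at a log2 difference of 1.49 (SE 0.27), and Cd34, at -0.96 (SE 0.18), both with a limma adjusted p of 0.0611 and so not past the threshold. In the list of red cell genes, Tspo2 had a log2 difference of 1.51 and an adjusted p of 0.0611 in limma. In the list of cholesterol genes, Cyp51 was higher by 0.78 (SE 0.15), Nsdhl by 0.64 (SE 0.13) and Msmo1 by 0.55 (SE 0.14) on the log2 scale, with limma adjusted p of 0.0611, 0.0871 and 0.293.

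**Figure D2:**
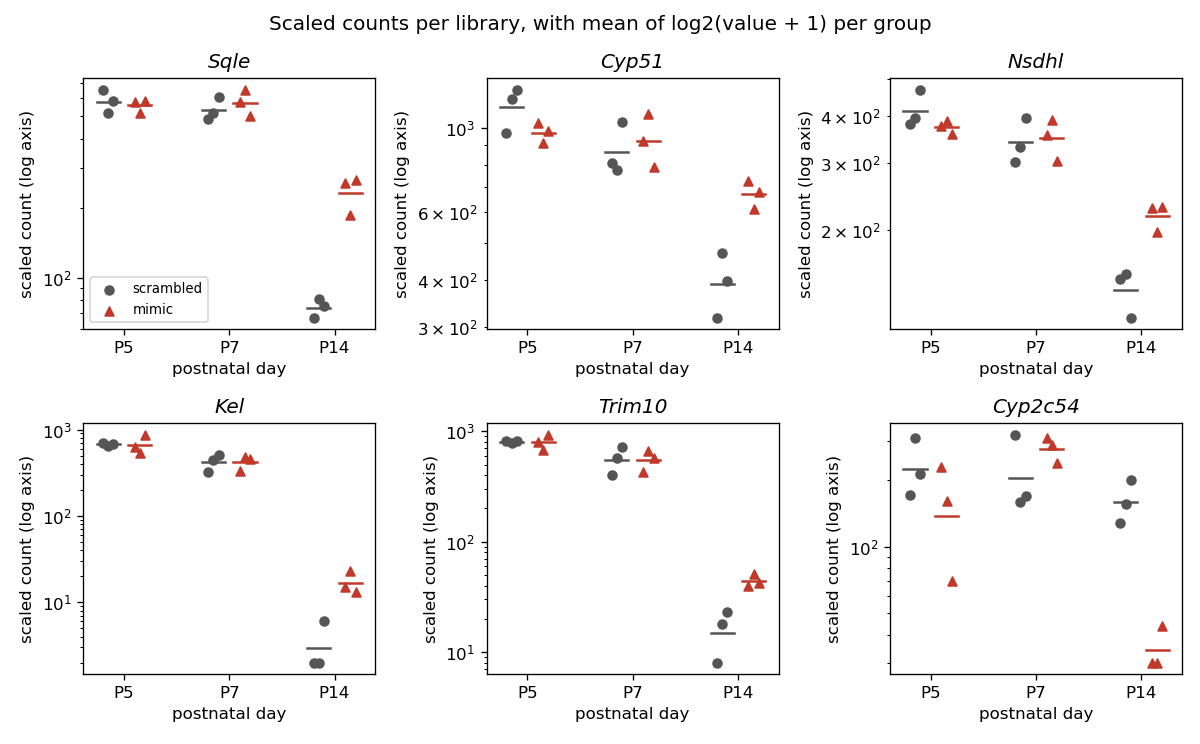
Scaled counts (y axis, log scale) of 6 genes in each library by postnatal day, grey circles for scrambled and red triangles for mimic; bars are means of log2(value + 1) per group, n = 3. At P14 all 3 mimic livers lie above all 3 scrambled livers for Sqle, Cyp51, Nsdhl, Kel and Trim10, and below them for Cyp2c54.

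Of 33 gene lists fixed beforehand, 14 passed an adjusted p of 0.05 in limma's camera test with its preset correlation of 0.01 at P14, 6 higher and 8 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.223, or in limma's fry test, where it was 0.117. The red cell list had a median log2 difference of 0.55 over 23 genes, with 20 of them higher. By limma, 1 of its genes passed over all genes tested and 12 were higher when adjusted over the list alone. The cholesterol list had a median of 0.19 over 24 genes, 21 of them higher, with 1 past the threshold over all genes and 7 adjusted over the list alone. In both lists the mean of all 3 mimic livers lay above that of all 3 scrambled livers, for an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 can give. Genes of the response to oxidative and foreign compounds, led by Nqo1 at -0.53, had a median of -0.15 over 20 genes and parted the libraries in the other direction, again at an exact p of 0.1.

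The neutrophil list had a median log2 difference of 0.57 at P14 and all 20 genes higher, 6 of them past 0.05 when adjusted over the list alone by limma and 0 over all genes. Mpo was higher by 1.29 (SE 0.36) and Elane by 0.97. The fibroblast and stellate cell list had a median of -0.27 with 18 of 19 genes lower, led by Acta2 at -0.80 (SE 0.22). The list means of the 2 groups overlapped in both cases, with exact permutation p of 0.2 and 0.3. The B cell list had a median of 0.58 with 13 of 15 genes higher (exact p 0.2). The urea cycle list leaned lower at P14, with a median of -0.16, 17 of 18 genes lower and overlapping list means (exact permutation p 0.2). Of the 33 list means, 4 parted the P14 libraries completely, where 3.3 would by chance with independent lists. The last of these 4 was the circadian clock list, with a mean difference of -0.091 (exact permutation p 0.1).

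At P7, most transcripts of platelet precursors and of amino acid breakdown leaned higher in mimic livers and most of sinusoidal endothelium and macrophages leaned lower. None of these genes passed the threshold over all genes, and no list passed with an estimated correlation or in fry. The only gene past it was the muscle gene Ttn, high in 2 of the 3 scrambled libraries. With limma, 1 gene passed an adjusted p of 0.05 and 1073 had an unadjusted p under 0.05. Ttn had 159, 14 and 301 scaled counts in the 3 scrambled libraries and 1, 0 and 1 in the mimic libraries, with a log2 difference of -5.82 (SE 0.85, limma adjusted p 0.0248). The highest of the other 15 libraries had 4. In P7 scrambled replicate 1, further muscle genes were high (Acta1 436, Myh8 344, Tnnt3 261 and Ckm 252), and in P7 scrambled replicate 3 the 3.08 per kb found at silent genes, times a Ttn transcript of 107 kb, came to 329. No gene passed without P7 scrambled replicate 3 or without any 1 of the 3 mimic libraries, while 7 other genes (6 higher, 1 lower) and not Ttn (limma adjusted p 0.0588) passed with only the 6 P7 libraries in the fit. In leave-one-out fits, 13 passed without P7 scrambled replicate 1 and 9 without P7 scrambled replicate 2.

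The next smallest p at P7 belonged to Retsat, Proser2, Hmcn2 and Rdh16, none past the threshold. Retsat was at 789 ± 32.0 in scrambled and 518 ± 12.5 in mimic livers (SD, n = 3 each), a log2 difference of -0.61 with a limma adjusted p of 0.0759. Proser2 and Rdh16 were higher by 0.79 and 0.86 on the log2 scale, and the limma adjusted p of Proser2 was 0.0961. Hmcn2, a long transcript at 62 in P7 scrambled replicate 3 and 29 in replicate 1, was lower by 2.70.

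In camera with the preset correlation, 14 of the 33 lists passed at P7, 7 higher and 7 lower, and none passed with an estimated correlation (smallest adjusted p 0.494) or in fry (0.334). The platelet list had a median log2 difference of 0.82 with 13 of 14 genes higher; 0 passed over all genes and 8 adjusted over the list alone in limma. Itgb3, Itga2b, Treml1 and F2rl2 were higher by 0.68, 0.74, 1.07 and 1.09. The list of urea cycle and amino acid breakdown had a median of 0.22 with 17 of 18 genes higher, 8 of them past 0.05 when adjusted over the list alone and 0 over all genes. Gpt was higher by 0.98 (SE 0.22) and Hal by 0.75. The sinusoidal endothelium list had a median of -0.22 with 16 of 17 genes lower, and the macrophage list one of -0.13 with all 18 lower. The B cell list had a median of 0.46 with 13 of 15 genes higher. In these 5 lists the 3 mimic livers lay on 1 side of the 3 scrambled livers, an exact permutation p of 0.1 each, the smallest possible. The mitosis list had a median of -0.18 with all 25 genes lower and overlapping list means (exact permutation p 0.4). Its camera adjusted p was 5.93e-06 with the preset correlation and 0.507 with an estimated one. Without P7 scrambled replicates 2 and 3 the median of this list turned to 0.062. In all, 9 of the 33 list means parted the P7 libraries, where 3.3 would by chance with independent lists. The list of pancreas, gut, muscle and fat genes also parted the libraries, with a median of -0.87 and muscle genes among its members, and so did fatty acid oxidation, where the median was -0.02 and the mean -0.15.

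**Figure D3:**
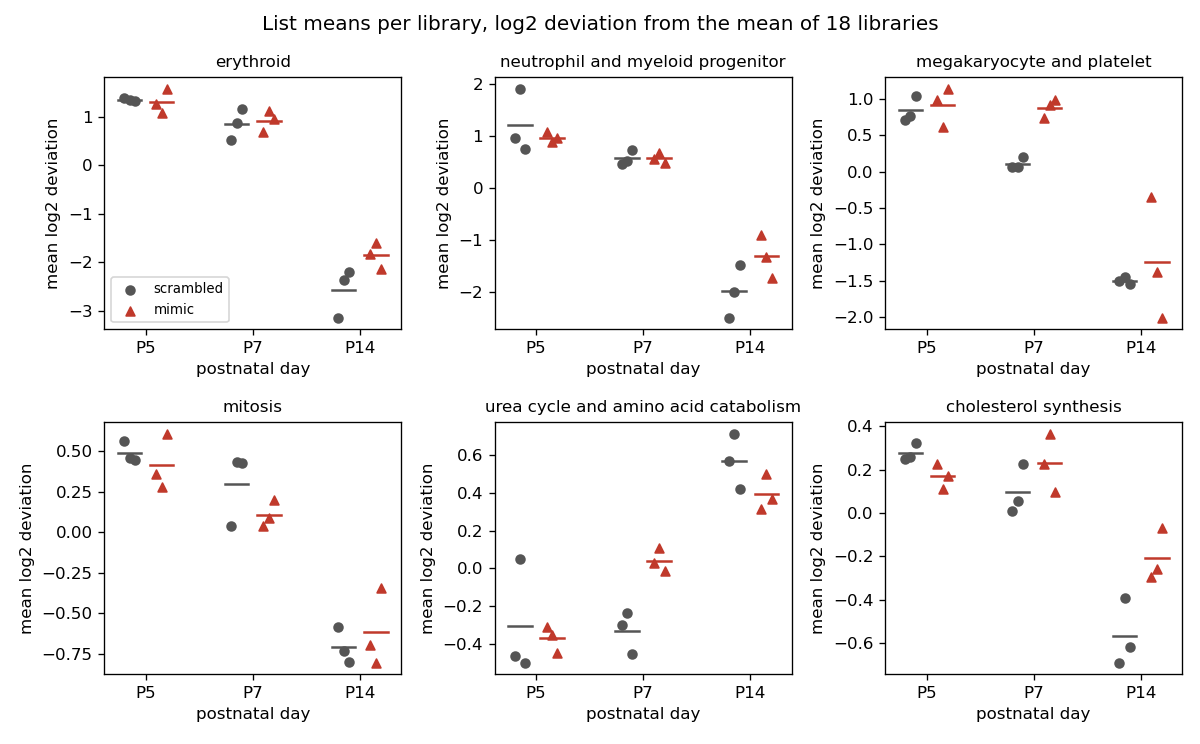
Mean log2 deviation of 6 gene lists from the mean of the 18 libraries (y axis) by postnatal day, 1 point per library, grey circles for scrambled and red triangles for mimic; bars are group means, n = 3. The platelet list lies between 0.74 and 0.99 in the P7 mimic livers and between 0.06 and 0.20 in the P7 scrambled livers.

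At P5, 2 days after the second injection, no gene differed past the threshold. The genes with the smallest p were Itga7, Prss35, Sult1c2 and Dcx, higher in mimic livers, and Cyp2c55, lower. Limma called 0 genes at an adjusted p of 0.05, and 266 of 14104 had an unadjusted p under 0.05. Without P5 scrambled replicate 1, limma called 1 gene and 854 had an unadjusted p under 0.05. Log2 differences were 0.79 for Itga7, 1.00 for Prss35, 0.50 for Sult1c2, 1.43 for Dcx and -1.73 for Cyp2c55, each at an adjusted p of 1. Camera passed 8 lists with the preset correlation, 3 higher and 5 lower, and none with an estimated one (smallest adjusted p 0.869) or in fry (0.987). The interferon list was lower by a median of 0.20, with 25 of 26 genes lower and list means that overlapped between groups (exact permutation p 0.3). The cholesterol list had a median of -0.11 with 21 of 24 genes lower and parted the libraries at an exact p of 0.1. At P7 its median was 0.11 with 21 of 24 genes higher (camera adjusted p 0.000402 with the preset correlation, 0.507 with an estimated one, 0.463 in fry, exact permutation p 0.2). The difference between the mimic effects at P5 and P7 passed for this list in camera with the preset correlation (adjusted p 6.18e-06), but not with an estimated one (0.733) or in fry (0.756). The cholesterol list was the only 1 of the 33 to part the P5 libraries, where 3.3 would by chance with independent lists.

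Averaged over the 3 days, Sqle alone passed an adjusted p of 0.05 in limma, at a log2 difference of 0.56 (SE 0.08, adjusted p 0.0131), and 457 genes had an unadjusted p under 0.05. The call was lost with the red cell covariate (smallest adjusted p 0.179), with no mean-variance trend (0.113), and without P5 mimic replicate 1 or 3, P14 scrambled replicate 1 or P14 mimic replicate 1. Its effect at P14 was the only part of that average to stand apart: the log2 difference of Sqle was -0.05 at P5 and 0.11 at P7. Sqle was also the only gene whose mimic effect differed between days in limma's F test (adjusted p 0.000748), with 917 genes at an unadjusted p under 0.05. Kel had an adjusted p of 0.207 and Cyp2c54 one of 0.279 in that test, so a difference between days was not shown for them. The 4 genes next in the average, Ttn (-2.57), Lrtm1 (0.92), Nat8f2 (0.42) and Ihh (0.71), did not pass. Of the 33 list means, the B cell list had the smallest stratified exact permutation p over the 3 days, 0.0380, two-sided, and 0.516 after adjustment over the lists.

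No lowering of transcripts with sites for the microRNA's seed was detected in mimic livers at any day. The seed, nucleotides 2 to 8, reads AGCAGCA, and 3231 of the tested genes carried its 7-mer match TGCTGCT in their longest annotated 3′ UTR while 9959 did not. The median log2 difference of genes with a site was -0.0087 at P5, 0.0087 at P7 and -0.0059 at P14, and of genes without one -0.017, -0.0086 and 0.0032. Camera p for the shift were 0.593, 0.478 and 0.657 with the preset correlation and 0.771, 0.700 and 0.809 with an estimated one, and 126, 165 and 146 of 209 other 7-mers of the same base composition had a lower shift. In 605 genes with the 8-mer TGCTGCTA, the difference from genes without it was 0.0053, 0.022 and -0.0042. With 1 library left out, the preset correlation passed 2 shifts, both toward higher values in mimic livers. Without P5 scrambled replicate 1 the median was 0.037 with a site and -0.0098 without (camera p 0.0140, and 0.130 with an estimated correlation). Without P7 mimic replicate 2 the medians were 0.015 and -0.027 (0.0471 and 0.285). When values of all genes with a 7-mer site were lowered by 0.1 on the log2 scale in the mimic libraries of 1 day, the camera p with estimated correlation was 0.00149 at P5, 0.0121 at P7 and 0.00272 at P14. A lowering by 0.05 gave 0.0762, 0.223 and 0.0656 with that test, and 0.000504, 0.0213 and 0.000280 with the preset correlation. By exact permutation of the libraries' shifts, a lowering by 0.05 gave p of 0.5, 0.6 and 0.1. Every site gene was lowered by the same amount, so these figures do not cover a lowering of only some of them.

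**Figure D4:**
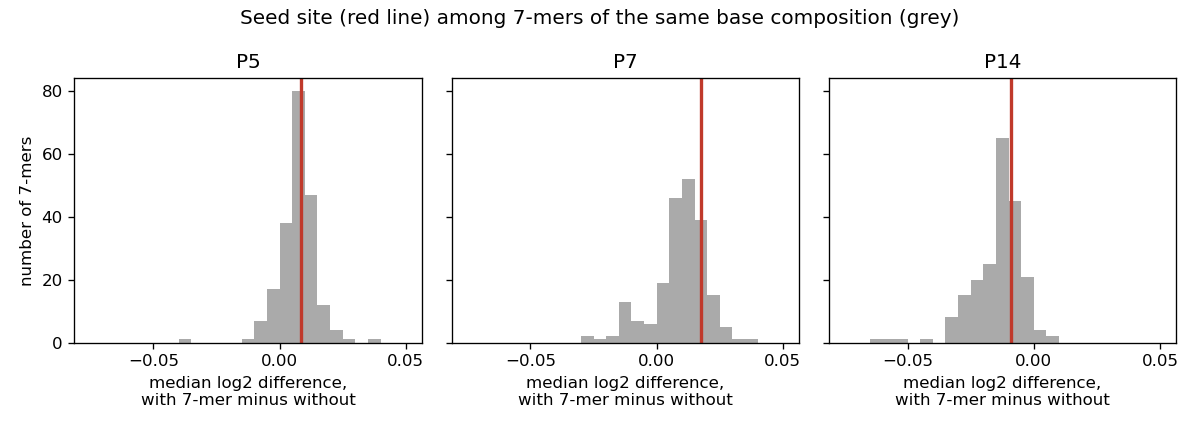
Number of 7-mers (y axis) by the median log2 difference between mimic and scrambled of genes with the 7-mer in their 3′ UTR minus that of genes without it (x axis), 209 7-mers in grey and the seed site as a red line, at each day. The line lies inside the grey distribution at P5, P7 and P14.

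None of the 10 genes named as targets of the miR-15, miR-16 and miR-497 family, which act in the cell cycle, survival and vessel growth, differed past the threshold. Of Ccnd1, Ccnd2, Ccnd3, Ccne1, Cdk6, Wee1, Chek1, Cdc25a, Bcl2 and Vegfa, 0 of 10 passed at any day in limma, over all genes or adjusted over the list alone. Their log2 differences ran from -0.19 to 0.41 at P5, from -0.12 to 0.12 at P7 and from -0.36 to 0.20 at P14. The farthest were Bcl2 at P5 (0.41, SE 0.18, limma adjusted p 1) and Ccnd2 at P14 (-0.36, SE 0.13, limma adjusted p 0.725). Afp, at 0.873 reads per base, differed by -0.08 at P5, -0.06 at P7 and -0.22 at P14, none past the threshold. Alb differed by -0.10, -0.01 and -0.05, and no absence of change is read from it, since its read number stayed between 2017 and 2130 in all 18 libraries.

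Between P7 and P14, most red cell, neutrophil, platelet and mitosis genes fell in scrambled livers, and most urea cycle genes rose. No list passed in camera with an estimated correlation (smallest adjusted p 0.218). In limma, 4765 of 14104 genes passed an adjusted p of 0.05, 2032 higher and 2733 lower at P14, and 6201 had an unadjusted p under 0.05. The balance turned with TMM scaling (2585 higher, 2379 lower), quantile normalization (2614 and 2324) and the length trend removed (3799 and 2137). The count was 1508 without P7 scrambled replicates 2 and 3 and 0 with the red cell covariate, which itself falls with age. Among the largest rises of genes with a mean of 100 or more were Cyp2c29, at a log2 difference of 5.36, Ntrk2 (4.15), Slco1a4 (3.36), Sult2a5 (2.95), Gpt (2.81), H2-Q1 (2.76), Slc1a2 (2.74), Upp2 (2.37) and Slco2b1 (2.36). The largest falls were Kel (-6.72), Apol8 (-6.44), Hemgn (-6.34), Btnl10 (-6.29), Add2 (-6.07), Slfn14 (-5.99), Gfi1b (-5.89), Epb42 (-5.70), Pkhd1l1 (-5.66) and Ypel4 (-5.65).

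Among the lists, 22 passed in camera with the preset correlation between P7 and P14, 9 higher and 13 lower, and 21 in fry, against none with an estimated correlation. The median log2 difference of the red cell list was -4.11, with 18 of 23 genes past the threshold, and that of the neutrophil list -2.22, with all 20 past it. The platelet list had a median of -1.64 and the mitosis list one of -0.96, with all 14 and all 25 genes past the threshold. Mki67 fell from 2401 ± 667 to 669 ± 55.7 (SD, n = 3 each). In the fetal list, Dlk1 fell from 365 ± 26.3 to 45.3 ± 22.2 (SD, n = 3 each), and 11 of 17 genes passed. The mature hepatocyte list had a median of 0.36, with 12 of 24 genes higher past the threshold and 2 lower (adjusted p 0.286 in camera with an estimated correlation and 0.00116 in fry). The cholesterol list had a median of -0.44, with 13 of 24 genes lower past the threshold and 2 higher. The urea cycle list had a median of 0.66 with 16 of 18 genes past the threshold. Of the 10 targets named above, 6 passed, with Ccne1 at -1.30 and Vegfa at 0.39. Afp had a log2 difference of -0.37 and Alb of 0.20, neither past the threshold. The nearly fixed read number of Alb leaves its change with age unmeasured. Afp lay at 0.873 reads per base and reached 2082 reads over a transcript of 2063 bases, so its fall may be understated.

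Between P5 and P7 no gene passed in scrambled livers, although 3265 of 14104 had an unadjusted p under 0.05 in limma. Leaving out P5 scrambled replicate 1 gave 2342 genes, 1239 higher and 1103 lower, and leaving out P5 scrambled replicate 2, P7 scrambled replicate 1 or P7 scrambled replicate 2 gave 2, 8 and 7. With all libraries, quantile normalization gave 113 genes, 73 higher and 40 lower, a pseudocount of 5 gave 9 and the length trend removed gave 3. P5 scrambled replicate 1 had a rank correlation with transcript length of 0.256, where the other 2 scrambled libraries of that day had -0.429 and -0.316 and the P7 scrambled libraries had 0.210 to 0.529. Camera passed 12 lists with the preset correlation, 3 higher and 9 lower, none with an estimated one (smallest adjusted p 0.585) and none in fry (0.211). The platelet list had a median of -0.73, the neutrophil list -0.62 and the red cell list -0.53.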

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

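The tests of explanations in this part were chosen after the results they address were seen; the counts of other splits were planned.

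Sqle is listed here because its mimic effect differed between the 3 days (limma F test, adjusted p 0.000748). Together with Kel and Cyp2c54 it made up the calls at P14. Removing each library's trend with transcript length left 3 of the 3 genes past the threshold, and so did a covariate for Y-linked genes, which argues against length bias and against the mix of male and female pups as the whole cause. With the mean of red cell genes as a covariate, Sqle kept a log2 difference of 1.54 (SE 0.18, limma adjusted p 0.00148) against 1.64 without it, so red cell content as measured here does not account for Sqle. Covariates for neutrophils and B cells, whose lists also leaned higher at P14, were not fitted. Cyp2c54 went from -2.18 (SE 0.34) to -1.82 (SE 0.44) with an adjusted p of 0.402: the difference shrank little and its error grew, and red cell content and the mimic cannot be told apart for this gene. For Kel, 19 of the 22 other red cell genes were also higher in P14 mimic livers, with a median of 0.50, and their mean parted the libraries (exact permutation p 0.1, the smallest possible). With the red cell covariate, Kel itself fell to 1.37 with a limma adjusted p of 0.160. Part of that fall is by construction, since Kel is among the genes whose mean is the covariate. More red cell precursors left in these livers is a candidate explanation for Kel. An effect of the mimic, the litter of the pups and their feeding state stay open for Sqle, and none of these was tested beyond the group labels.

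Other splits of the libraries bear on these counts. For P14, 3 of the 10 splits of the 6 libraries gave 3 or more genes and the highest other split gave 8; for P7 the real split gave 1 gene and the highest other 0; for P14 against P7 the real split gave 4765 and the highest other 0, which is 1 split of 10. With 3 against 3 the splits are too few for a share under 0.05. At P14 other splits reached the real count as well, so chance cannot be excluded for that count of 3 genes. At P5, and for P7 against P5 in scrambled livers, the real count was 0, which all 10 of 10 splits reach by definition, so the comparison tests nothing there (highest other 1 and 18). For the average over days, 13 of 100 regroupings within days gave 1 or more genes, with 455 in the highest other, and for the difference between days 18 of 100 did, with 125 in the highest other, so chance cannot be excluded for either count.

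P7 scrambled replicates 3 and 2 are listed because genes silent in the other 16 libraries carried values there, 3.08 and 0.168 scaled counts per kb. In replicate 3, 99.4% of 8686 such genes were above 0, against 22.6% in replicate 2 and at most 4.35% elsewhere, and the rate lay between 1.93 and 4.42 per kb on the autosomes and at 1.97 on X. The genes were picked for low values in those 16 libraries, so part of this contrast is built in. Over all genes of the table, with no such choice, 30412 were above 0 in replicate 3, 22132 in replicate 2 and at most 20418 elsewhere. The Ttn call at P7 was weighed against the values at silent genes. The background times the length of Ttn gives 329 in replicate 3 where 301 was found, and subtracting it in all libraries moved the log2 difference of Ttn from -5.82 to -2.43 (adjusted p 0.719). Across the silent genes of replicate 3, Spearman's rho between value and transcript length was only 0.368, so the 329 is a rough figure. In replicate 1, the 4 muscle genes Acta1, Myh8, Ckm and Tnnt3 were at 6.87 or more times their highest value in the other 17 libraries. Reads spread along all genes in replicate 3, as DNA would give, and a trace of muscle in replicate 1 are consistent with the Ttn values, and no part of the call then needs the mimic. A biological fall of Ttn in liver was not tested.

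Some abundant transcripts, such as Alb, Apoa1 and Apoe, held nearly the same number of reads in every library. Others did not: Afp ran from 1058 to 2082 reads and Apob from 2699 to 8686. Across 24 genes above 0.8 reads per base with transcripts of 500 bases or more, the mean log2 value followed the log2 worth of 1 read with Pearson's r of 0.991 and Spearman's rho of 0.966 over 18 libraries (permutation p 1e-05 each, the smallest possible with the draws made). The first test asked whether the slope lay within a set bound of 1; it was 0.84 and left the matter undecided, and r was 0.981 without P5 scrambled replicate 2 and P7 mimic replicate 3. The second asked whether the median ratio of variance to mean was under 1; it was 1.28, against 32.6 in 1270 genes with 500 or more reads but under 0.2 reads per base, and was undecided too. The third, picked after those, counted genes whose read number varied by less than its counting error: 11 of the 24, against 0 of the 1270. Its outcome carries less weight for having been the third tried, and over 0.5 of the 24 genes varied by at least counting error. Among the genes looked at singly, 2 that the bounds of that test left out lay far below 1 read per base and also varied by less than counting error. Serpina1a, at 0.263 reads per base, had a CV of 2.40% where counting gives 4.90%, and Hba-a1, at 0.103, had 5.05% where counting gives 11.8%. As a hypothesis, a ceiling of about 1 kept read per position might account for part of the 11 genes, since the named tool Picard can remove duplicate reads. Reads per base were taken over the whole transcript, and how much of it can hold counted reads was not determined. These 2 genes therefore decide neither for nor against such a ceiling. The cause was therefore left open, and no biological explanation was tested. The SD of log2 differences between P7 and P14 was 0.16 in 202 genes above 0.5 reads per base and 0.67 in 6062 genes between 0.05 and 0.2.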

How the results depend on the processing

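Leaving out P7 scrambled replicates 2 and 3, subtracting background and removing the length trend were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, since the values are scaled and rounded. Unless a sentence says so, the cause of a change was not tested.

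At P5 limma called 0 genes under every other alternative, and 0 to 1 with each library left out (1 without P5 scrambled replicate 1). At P7, against 1 gene, the count was 3 with no filter, 0 with a mean of 50 or more, 4 with quantile normalization, 7 with only the libraries compared (6 higher and 1 lower, Ttn not among them), 0 with background subtracted, 0 with the length trend removed and 0 to 13 with each library left out (13 and 9 without P7 scrambled replicates 1 and 2 in turn, 0 without any of the other 4). It was 19 without P7 scrambled replicates 2 and 3, where the lone scrambled library is the one with muscle genes and is assumed to vary like the other groups. At P14, against 3 genes (2 higher, 1 lower), it was 5 with a pseudocount of 5, 11 with TMM scaling (6 higher, 5 lower), 7 with the sex covariate, 2 with only the libraries compared (Sqle and Cyp2c54), 1 with the red cell covariate and 3 to 16 with each library left out (15, 16 and 8 without P14 scrambled replicates 2 and 3 and P14 mimic replicate 3 in turn). The average over days gave 0 with the red cell covariate, 12 without P7 scrambled replicates 2 and 3, 0 with no mean-variance trend and 0 to 4 with each library left out. It was 0 without P5 mimic replicate 1 or 3, P14 scrambled replicate 1 or P14 mimic replicate 1, and 2 to 4 without P5 scrambled replicate 2, P7 scrambled replicate 1 or 2, P14 scrambled replicate 3 or P14 mimic replicate 3. The difference between days gave 12 without those libraries and 1 to 7 with each library left out, with 7 without P7 scrambled replicate 1 and 2 or 3 without P5 scrambled replicate 1 or 3, P5 mimic replicate 3, P7 scrambled replicate 2, P14 scrambled replicate 3 or P14 mimic replicate 3.

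P7 against P5 gave 9 with a pseudocount of 5, 113 with quantile normalization, 17 without P7 scrambled replicates 2 and 3, 3 with the length trend removed and 0 to 2342 with each library left out, the highest without P5 scrambled replicate 1. P14 against P7 gave 3398 to 4499 with each library left out, 1508 without P7 scrambled replicates 2 and 3, with fewer samples, and 0 with the red cell covariate, which itself falls with age. There were 2585 higher and 2379 lower with TMM scaling, 2614 and 2324 with quantile normalization and 3799 and 2137 with the length trend removed, against 2032 and 2733; the last moved the median of all genes to 0.13.

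With the replicate number as a block, 3 genes passed at P7 and 7 at P14. Same-numbered livers showed no clear common deviation (correlations from -0.23 to 0.24, with 4 of the 9 scrambled livers nearest to their own number). With so few livers per group this check cannot exclude that the numbers pair the samples, and the labels do not give litters. The block changed no other count by over 1.5 times.

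Every named gene and list was recomputed under the alternatives that give it a value. Over all of these, genes kept their direction and side of the threshold in 2350 cases, fell short of it in 66, passed it in 43 and changed sign in 106; for list medians the numbers were 1052, 188, 0 and 20. Of the sign changes of genes, 86 were of the 10 targets, whose differences at the 3 days lay mostly near 0.

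Without P7 scrambled replicates 2 and 3, the sign changed at P7 for the mitosis list (0.062), the interferon-stimulated list (0.086), Ccne1 (0.35), Cdk6 (0.0087), Vegfa (-0.082), Afp (0.030) and Alb (0.077). With TMM scaling, the sign changed at P7 for the fatty acid oxidation and ketogenesis list (0.037), Ccnd1 (0.019), Ccnd2 (0.0074), Ccne1 (0.043), Cdk6 (0.014), Alb (0.048) and the target panel median (0.031). Between P7 and P14 it did so for Ccnd2 (0.020). With the length trend removed, the sign changed at P7 for the fatty acid oxidation and ketogenesis list (0.0089), Ccne1 (0.021), Cdk6 (0.010), Alb (0.025) and the target panel median (0.015). Between P5 and P7 it did so for the microRNA pathway list (-0.11). At P5 it did so for Ccne1 (-0.0054), Vegfa (-0.0023) and the target panel median (-0.0038). At P14 it did so for Cdk6 (0.065) and the seed-site genes (0.000946). Between P7 and P14 it did so for Ccnd2 (0.18), Cdk6 (0.038) and Bcl2 (0.13). With the erythroid covariate, the sign changed at P14 for the erythroid list (-0.086), Ccnd1 (0.15), Cdk6 (0.12), Chek1 (-0.21), Vegfa (0.10) and the target panel median (0.024). Between P7 and P14 it did so for the DNA replication and G1/S list (0.035), the erythroid list (0.038), the B cell list (0.45), the circadian clock list (-0.062), Slc1a2 (-0.12), Apol8 (0.22), Btnl10 (0.10), Add2 (0.85), Epb42 (2.57), Pkhd1l1 (1.41), Ccnd2 (0.40), Ccnd3 (0.090), Chek1 (0.63), Bcl2 (0.23) and Vegfa (-0.15). At P5 it did so for Vegfa (-0.0043). At P7 it did so for Wee1 (-0.0047) and Chek1 (-0.0056). With quantile normalization, the sign changed at P14 for the fatty acid oxidation and ketogenesis list (7.61e-06), Ccnd1 (0.050), Cdk6 (0.0035), Chek1 (-0.018), Vegfa (0.034) and Alb (0.065). At P5 it did so for Ccnd3 (0.025) and Afp (0.047). At P7 it did so for Ccnd3 (-0.0075). Between P7 and P14 it did so for Bcl2 (0.067). With the sex covariate, the sign changed at P5 for Ccne1 (-0.057), Wee1 (-0.013) and the target panel median (-0.024). At P7 it did so for Ccne1 (0.023). At P14 it did so for Ccnd1 (0.011) and Wee1 (0.034). With background per kb subtracted, the sign changed between P7 and P14 for Bcl2 (0.012). The red cell list and its genes change by construction with their own mean as covariate.

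At P5 the ranges with each library left out were -0.37 to 0.098 for the neutrophil and myeloid progenitor list, -0.10 to 0.39 for the B cell list, -0.17 to 0.080 for the urea cycle and amino acid catabolism list, -0.22 to 0.057 for the ribosomal protein list, -0.14 to 0.029 for Sqle, -0.10 to 0.038 for Ccnd3, -0.058 to 0.14 for Ccne1, -0.16 to 0.086 for Cdk6, -0.081 to 0.090 for Wee1, -0.11 to 0.14 for Vegfa, -0.21 to 0.075 for Afp, -0.24 to 0.074 for Alb, -0.030 to 0.035 for the target panel median and -0.029 to 0.037 for the seed-site genes, the last without P5 scrambled replicate 1 and with a camera p of 0.0140. At P7 the ranges with each library left out were -0.37 to 0.016 for the T and NK cell list, -0.10 to 0.0099 for the fatty acid oxidation and ketogenesis list, -0.073 to 0.0053 for Ccnd1, -0.025 to 0.13 for Ccnd3, -0.20 to 0.12 for Ccne1, -0.099 to 0.016 for Cdk6, -0.045 to 0.039 for Wee1, -0.14 to 0.15 for Chek1, -0.027 to 0.22 for Vegfa, -0.17 to 0.047 for Afp, -0.12 to 0.094 for Alb and -0.0038 to 0.022 for the seed-site genes, with a camera p of 0.0471 at 0.015 without P7 mimic replicate 2. At P14 the ranges with each library left out were -0.047 to 0.21 for the mitosis list, -0.14 to 0.64 for the megakaryocyte and platelet list, -0.11 to 0.11 for Ccnd1, -0.10 to 0.040 for Ccnd3, -0.13 to 0.48 for Ccne1, -0.088 to 0.068 for Cdk6, -0.094 to 0.061 for Wee1, -0.13 to 0.14 for Chek1, -0.025 to 0.24 for Cdc25a, -0.23 to 0.039 for Bcl2, -0.060 to 0.021 for Vegfa, -0.091 to 0.051 for the target panel median and -0.020 to 0.017 for the seed-site genes. Between P7 and P14 the ranges with each library left out were -0.18 to 0.055 for Ccnd2.

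Genes with a mean under 10 were tested only in the alternative with no filter, and the low estimated read numbers limit what can be said of them.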

Other observations

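The test of the hypothesis below was chosen after the component scores of the livers had been seen.

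A hypothesis was that livers given the mimic mature more slowly, since most red cell, neutrophil and cholesterol genes, groups that fall between P7 and P14, leaned higher in mimic livers at P14, with only Kel and Sqle past the threshold. In the fetal list, 11 of 17 genes also fell past the threshold between P7 and P14. At P14 its median was -0.095 with 12 of 17 genes lower in mimic livers, but its mean was higher by 0.031. The list means of the groups overlapped (exact permutation p 0.9), so this list leaned clearly to neither side. At P14 the urea cycle list, which rises with age, was lower in mimic livers by a mean of 0.17 (exact permutation p 0.2). All 4 lists that parted the P14 libraries leaned toward the P7 state. Besides the red cell and cholesterol lists, these were the oxidative and foreign compound list (-0.23) and the clock list (-0.091), which rise. The NF-kB list, which falls, leaned away from it (-0.11, exact permutation p 0.4). At P7 the leans were mixed. The urea cycle list, which rises between P7 and P14, was higher in mimic livers by a mean of 0.37 (exact permutation p 0.1), the opposite of slower maturation. The mitosis and fetal lists, which fall, had mean differences of -0.19 and -0.21 (exact permutation p 0.4 and 0.2). The platelet list, which also falls, was higher by 0.77 (exact permutation p 0.1). Each P14 liver was placed on the axis from the mean of the P7 livers to the mean of the other 5 P14 livers over 9923 genes. The mean position was 0.922 ± 0.0305 in mimic and 1.02 ± 0.111 in scrambled livers (SD, n = 3 each), a difference of -0.096 with an exact permutation p of 0.4, two-sided. P14 scrambled replicate 3, at 0.891, lay nearer to P7 than all 3 mimic livers. The axis therefore leaves the hypothesis open, and 3 livers per group cannot settle it.

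Xist and Y-linked genes showed 9 livers of each sex pattern, unevenly spread over the groups. Some livers with Xist also held low Y-linked values. P5 mimic replicate 3 had Xist at 1568 with Ddx3y at 60 and Eif2s3y at 31, and P7 scrambled replicate 3 had Xist at 1484 with Ddx3y at 45 and Eif2s3y at 31. In P7 scrambled replicate 2, Ddx3y was at 786 with Xist at 66. In the other livers with Xist above 500, Ddx3y was at most 8.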
